A study of Mus musculus with 5 samples.

How the data were processed

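Ribosome-protected mRNA fragments (footprints) were measured in hippocampal-cortical brain slices of wild-type male C57BL/6N mice, 28 to 35 days old. Homoharringtonine (HHT) is a plant alkaloid that blocks the first rounds of elongation after initiation while ribosomes that are already elongating run off. Per the labels' protocols, slices of 400 µm recovered for 3 to 4 h, were exposed to 20 µM HHT for 0, 5, 10, 30 or 60 min, and were frozen. The vehicle was 0.05% DMSO. The series holds no library of slices with vehicle alone at 5 to 60 min. Changes with time on HHT therefore cannot be told apart from those of the vehicle or of any further time after slicing. Each pool held 10 slices from 2 to 3 mice. Lysates were treated with RNases A and T1, monosomes were taken from sucrose gradients of 10 to 50%, and 75 bp reads were sequenced. The 5 libraries form 5 groups of 1, so no time point has a replicate.

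Per the submitters' processing notes, cutadapt 1.7.1, Trimmomatic 0.32, Bowtie2 2.1.0, TopHat2 2.0.9 and SAMtools 0.0.19 were used with the mm10 build. The names of the deposited data add RSEM, with its settings not stated, and say that the CDS was taken without its ends. The role of each tool and the treatment of reads shared between near-identical genes are not given in the sources used here. The authors deposited a table of expected counts for 10329 genes, whole numbers as listed and rounded again here without change. These genes have coding sequences (CDS) of 603 to 24099 nt, and at least 11 counts at 0 min and 1 count at 5 min, so mRNAs with shorter CDS and genes read only after HHT do not appear in that table. The same deposited table gives a signal per gene that equals the count divided by the CDS length less 600 nt, in kilobases, and by 1 factor per library. Those factors were 1, 0.965, 0.828, 0.882 and 0.973 in time order, and their origin is not given in the sources used here. The deposited ratio columns divide that signal at each time by its value at 0 min, and the deposited score columns give the fraction lost between times; the latter were not used. A second deposited table gives a score for 18527 genes, a TPM rounded to whole numbers that sums to nearly the same total in each library (1000034 at 0 min). It holds mitochondrially encoded genes, which the count table does not. Of the 10329 transcripts, 10293 matched the GRCm38.p6 annotation, 10112 of them with the same symbol. Gene positions are from that annotation, which is the assembly behind mm10.

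Total counts were 7155147, 2787749, 2022152, 1504748 and 1346175 in time order, with median counts per gene of 208, 64, 47, 42 and 38. Counting error is therefore widest at 60 min. Intervals of folds are exact 95% conditional binomial intervals on the counts of single libraries, so they cover counting error only. Reads carried no stated molecular identifiers, so copies made in amplification could leave these intervals too narrow even for that. A gene with 0 counts at 60 min is given as a bound against 3 counts in that library, which is tighter than the end of its 95% interval, so that end is given beside it.

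The following choices were made before the data were examined. The main test was the slope of each gene on log2(minutes + 1) over the 5 libraries, by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, a mean of at least 10 counts (9444 genes) and Benjamini-Hochberg adjusted p under 0.05. Its 3 residual degrees of freedom hold library scatter and departures from a straight line together. TMM scaling sets the typical gene level, so these slopes and folds are relative to other mRNAs and do not show a loss common to all of them. Another scaling, also chosen beforehand, set each library to mitochondrially encoded proteins, which are made by mitochondrial ribosomes that HHT does not target. It used the summed TPM of 6 genes, mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Co1 and mt-Cytb, carried to the count scale. The resulting factors differ from the deposited library factors by 2.44%, -0.38%, -1.18% and -0.17% at 5, 10, 30 and 60 min, so both are nearly 1 scaling. The 6 genes were picked after their levels were seen. Log2 folds of each time against 0 min used TMM-scaled CPM with a prior count of 2 and carry no p-value. Genes at least 2-fold apart were counted among those with at least 100 counts in both libraries together. All 4 folds share the single 0 min library.

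A set of 29 gene lists was fixed, of which 26 had at least 5 measured members. The mitochondrially encoded list (0 of 13 members in the count table), histones (3 of 20) and blood, choroid plexus and ependymal markers (3 of 18) were not tested. Each list has its median log2 fold, a percentile of that median among 10000 random lists of the same size matched on expression, and camera (limma 3.58.1) on the slope with a preset correlation of 0.01, adjusted over the 26 lists. Alternatives were random lists matched also on CDS length, camera with an estimated correlation, and fry. Genes were named by 4 rules. These were up to 12 steepest each way past the adjusted p; the 10 highest and 10 lowest folds at 60 min with at least 100 counts in both libraries together and 1 sign at all 4 times; up to 2 highest and 2 lowest members per list; and 12 fixed genes. Some genes that these rules select are not reported here.

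The distance cleared by running ribosomes was fitted to the deposited ratios as a step along the CDS, with 300 nt left out at each end. On simulated counts for the slope over 5 libraries (9333 genes), 1.56% of genes changed 2-fold at 60 min, 57.6% changed 4-fold and 100% changed 16-fold were recovered, with 3 unchanged genes called. For camera on that slope (9333 genes) 2 of 2 changed lists and 0 of 40 unchanged lists were called. Genes were drawn independently there, so this check does not cover correlation between the members of a list. For the run-off fit (8391 genes), simulated distances of 1000, 2000 and 4000 nt came back as 1000, 2000 and 4050 nt. Those ratios were drawn from the same step model, without an error of the library factors. Alternatives covered normalization, count filters, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), the time scale, each library left out, and the unit. The library factors of the deposited signal, the CDS length column, a camera with the length trend removed and the trimmed end were added after the data were seen. Figures were drawn with matplotlib 3.10.9.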

Results

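The 5 libraries cover 0, 5, 10, 30 and 60 min of 20 µM HHT in wild-type slices, with 1 pool per time point. Total counts were 7155147 at 0 min, 2787749 at 5 min, 2022152 at 10 min, 1504748 at 30 min and 1346175 at 60 min. The series addresses how ribosomes leave different mRNAs once new rounds of translation are blocked, and which mRNAs keep footprints. No difference between single time points has a replicate check, so no p-value is given for one; p-values are those of slopes over all 5 libraries.

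The first comparison asks how much of the footprint signal of cytosolic mRNAs was left at each time. Footprints of nearly all measured mRNAs fell. In the authors' deposited table the median ratio to 0 min over 10329 genes was 0.333 at 5 min, 0.268 at 10 min, 0.223 at 30 min and 0.181 at 60 min. Its quartiles at 60 min were 0.134 and 0.245, and 1 gene, the matrix protein gene Cilp2, had a ratio above 1 at that time (1.01). Transcripts of the mitochondrial genome moved the other way as a share of all footprints. The TPM of mt-Co1, a subunit of cytochrome c oxidase, was 1241 at 0 min and 6230 at 60 min, and that of mt-Cytb, of complex III, was 1253 and 5868. The summed TPM of 6 such genes was 3.42 times its 0 min value at 5 min, 3.50 times at 10 min, 4.09 times at 30 min and 4.92 times at 60 min. The inverses of these values, 0.293, 0.285, 0.245 and 0.203, are set beside the deposited medians. Factors computed here from these 6 genes differed from the library factors behind those medians by 2.44%, -0.38%, -1.18% and -0.17%. The 2 series are therefore on nearly the same scale and are no independent check of each other.

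**Figure D1:**
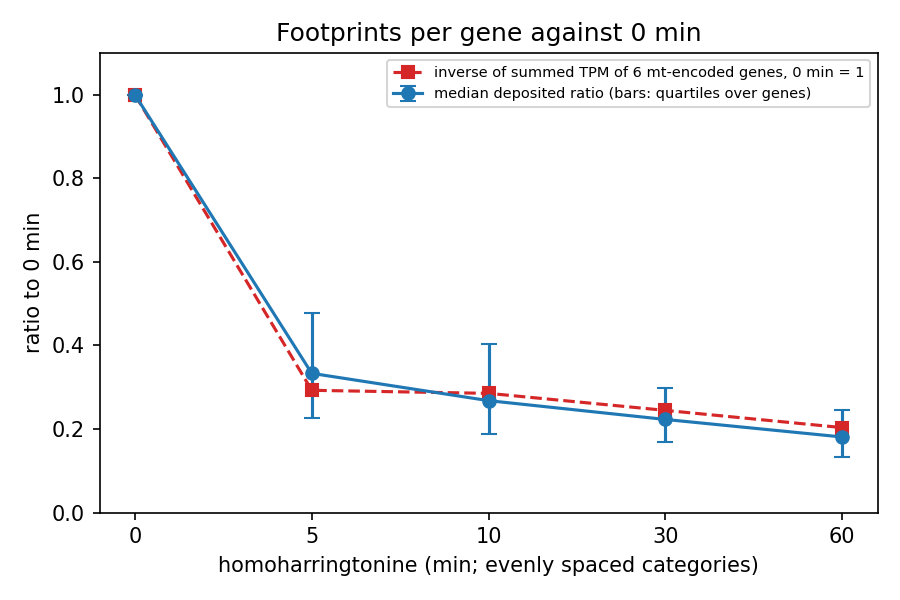
Ratio to 0 min (vertical axis, no unit) against minutes of HHT (horizontal axis, evenly spaced categories), 1 library per time. Circles are the median deposited ratio over 10329 genes with bars from the lower to the upper quartile, and squares are the inverse of the summed TPM of 6 mitochondrially encoded genes set to 1 at 0 min; both are near 0.2 at 60 min (0.181 and 0.203).

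With libraries scaled to mitochondrially encoded proteins, 8859 of 9444 genes fell along log2(minutes + 1) and 0 rose (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05); 8878 had an unadjusted p under 0.05 with a falling slope and 0 with a rising one. Camk2a, the kinase subunit of synaptic plasticity, fell by 0.36 log2 units per unit of log2(minutes + 1) (SE 0.077, adjusted p = 0.0012), and Actb, cytoplasmic actin, fell by 0.51 (SE 0.094, adjusted p = 0.00057). Among the genes with no call were Obsl1, a cytoskeletal adaptor gene (slope 0.0021, SE 0.077, adjusted p = 0.979), Phlda1 (-0.04, SE 0.074, adjusted p = 0.642) and Jph3, a junctophilin of neurons (-0.02, SE 0.071, adjusted p = 0.784). The deposited library factors, as an alternative added after the data were seen, gave 8900 lower and 0 higher; they lie so near the mitochondrial factors that this is nearly the same scaling again. Both scalings rest on 1 library per time and move every gene of a library by the same factor.

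The second comparison asks which mRNAs lost more or fewer footprints than the typical mRNA. Plek, which encodes pleckstrin of blood-derived cells and microglia (transcript NM_019549, chromosome 11, 16971206 to 17008718 in GRCm38), was the 1 gene called on the TMM-scaled slope, and it fell. It had 458 counts at 0 min, 24 at 5 min, 7 at 10 min, 3 at 30 min and 1 at 60 min, a log2 fold of -5.42 at 60 min with a counting interval of -11.66 to -3.87. Its slope was -1.04 (SE 0.078, adjusted p = 0.0018, edgeR quasi-likelihood test), and it was lower at 4 of 4 treated times. No gene was called higher; 637 genes with a rising slope and 518 with a falling one had an unadjusted p under 0.05. DESeq2's Wald test called 36 higher and 37 lower, and limma on log2(TPM + 1) called 0 and 0. Without the 0 min library the counts were 364 higher and 854 lower, without the 5 min library 0 and 0, without the 10 min library 2 and 18, without the 30 min library 0 and 2, and without the 60 min library 0 and 9.

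Among the other genes with the lowest folds at 60 min were several that encode immune receptors. C5ar1, the complement C5a receptor, had 138 counts at 0 min and 0 at 60 min, at least 8.20-fold lower after scaling against a floor of 3 counts, while its counting interval ends at a log2 fold of -2.72; its slope, -1.10 (SE 0.134), missed the threshold (adjusted p = 0.0578). The log2 folds of C3ar1, another complement receptor, Cd14, a lipopolysaccharide co-receptor, and Il1a, the cytokine interleukin 1 alpha, were -3.42 (-5.27 to -2.40), -3.38 (-4.87 to -2.49) and -3.41 (-4.59 to -2.64). Tlr2, Gpr84, Laptm5 and Slfn2, each with 1 to 3 counts at 60 min, had folds of -3.46 (-6.11 to -2.26), -3.49 (-6.14 to -2.29), -3.37 (-9.57 to -1.74) and -3.33 (-9.53 to -1.70). At the other end were genes whose counts at 60 min were close to those at 0 min. Obsl1 had 154 counts at 0 min and 144 at 60 min (log2 fold 2.35, 2.05 to 2.73), Jph3 554 and 465 (2.23, 2.06 to 2.42), and Phlda1 588 and 458 (2.12, 1.95 to 2.31). Cilp2, Ptpmt1, Col3a1, Pgr, Ltk, Grin2c and Cables2 had folds of 2.39, 2.25, 2.23, 2.18, 2.17, 2.11 and 2.11. None of these genes apart from Plek passed the TMM-scaled slope test. Counts of genes at least 2-fold higher and lower were 466 and 440 of 7632 at 5 min, 988 and 427 of 7517 at 10 min, 293 and 331 of 7483 at 30 min, and 337 and 377 of 7424 at 60 min. Scaled to mitochondrially encoded proteins, the same counts were 0 and 5939, 1 and 6333, 0 and 7278, and 0 and 7311; the median log2 fold of all genes under that scaling was -1.58, -1.86, -2.12 and -2.43.

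**Figure D2:**
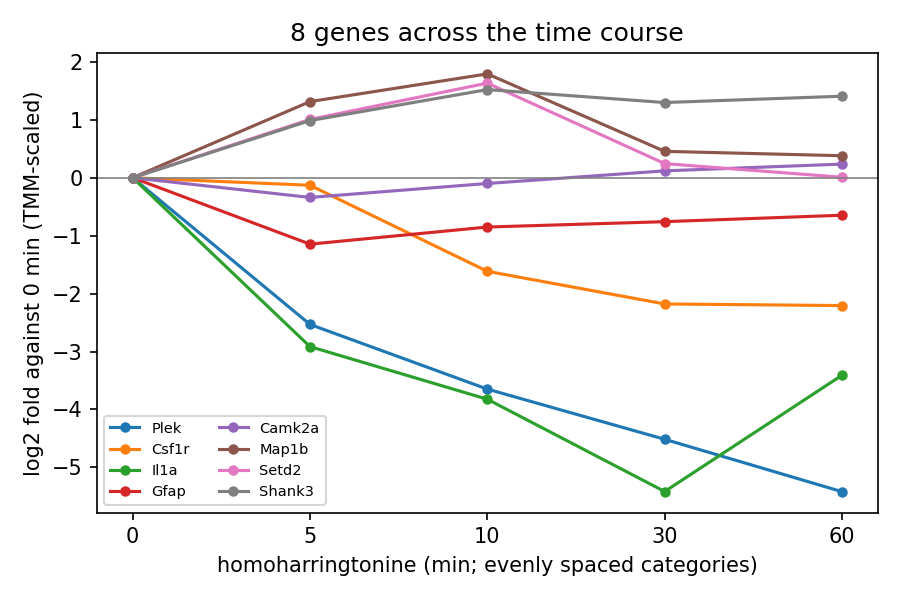
Log2 fold against 0 min (vertical axis, TMM-scaled, so relative to the typical mRNA) of 8 genes against minutes of HHT (horizontal axis, evenly spaced categories), 1 library per time, no error bars. Plek ends at -5.42 and Shank3 at 1.41, while Map1b and Setd2 peak at 10 min (1.79 and 1.63) and end at 0.38 and 0.01.

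The third comparison asks how footprint loss related to the length of the coding sequence. Long coding sequences had higher ratios than short ones at 5 and 10 min. Map1b, a microtubule-associated protein gene with a CDS of 7395 nt, had 30992, 24699, 23687, 8469 and 7183 counts in time order, with log2 folds of 1.31, 1.79, 0.46 and 0.38. Setd2, the histone H3 lysine 36 methyltransferase (CDS 7614 nt, chromosome 9, 110532500 to 110618633), had folds of 1.01, 1.63, 0.24 and 0.01, the last with an interval of -0.19 to 0.20. Actb (1128 nt) had folds of -1.36, -1.05, -0.74 and -0.67 relative to other mRNAs, while its ratio in the authors' deposited table was 0.129, 0.129, 0.135 and 0.115. Over the 1198 genes with a CDS of 603 nt to under 1000 nt, the median deposited ratio in the authors' deposited table was 0.200 at 5 min and 0.199 at 10 min, 0.205 at 30 min and 0.171 at 60 min. Over the 2201 genes of 1000 nt to under 1500 nt it was 0.246, 0.222, 0.214 and 0.177. Over the 1809 genes of 2000 nt to under 3000 nt it was 0.428, 0.281, 0.222 and 0.179, and over the 495 genes of 4000 nt to under 6000 nt it was 0.606, 0.604, 0.250 and 0.197. Over the 123 genes of 8000 nt or more it was 0.705, 0.866, 0.377 and 0.240. In this last group 111 of 123 genes had a higher deposited signal at 10 min than at 5 min, with a median ratio of 1.22.

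Across genes, Spearman's rho between log2 fold and effective CDS length was 0.715 at 5 min, 0.474 at 10 min, 0.118 at 30 min and 0.067 at 60 min (9057 genes, which are not independent replicates; no p-value was computed). A step fitted to the deposited ratios put the cleared distance at 1800 nt at 5 min and 2300 nt at 10 min, with remaining ratios of 0.26 and 0.23 behind the step. The fitted distance at 10 min was thus 1.28 times that at 5 min, with the deposited library factors taken as given. An advancing step cannot raise a ratio, yet the median of mRNAs of 8000 nt or more went from 0.705 at 5 min to 0.866 at 10 min. The 1.28 is therefore no measure of a change in elongation speed. The fitted distances were 1500 and 2000 nt, or 2100 and 2600 nt, when the nucleotides left out were taken from 1 end, alternatives added after the data were seen. The libraries at 5 and 10 min correlated with each other (rho 0.972), as did those at 30 and 60 min (rho 0.978), more closely than either with 0 min (rho 0.925 to 0.945).

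**Figure D3:**
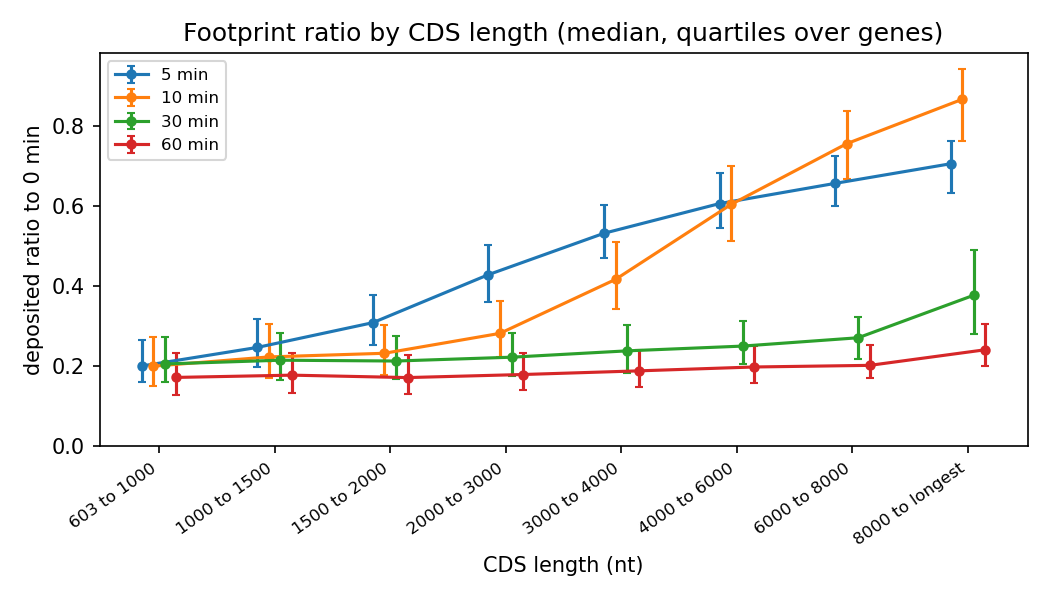
Deposited ratio to 0 min (vertical axis, no unit) by CDS length class in nt (horizontal axis), 1 line per time of HHT, 1 library each. Points are medians over the genes of a class and bars run from the lower to the upper quartile; at 5 and 10 min the medians climb from 0.200 and 0.199 in the shortest class to 0.705 and 0.866 in the longest, and at 60 min from 0.171 to 0.240.

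The fourth comparison asks whether gene groups fixed beforehand stood apart from other mRNAs. Glial and immune groups lost more footprints than the typical mRNA; rises and falls of lists are relative to it. Markers of microglia, the resident immune cells of the brain, had median log2 folds of -1.67, -1.89, -2.18 and -1.94 at 5, 10, 30 and 60 min. At 60 min 17 of 17 measured members (24 listed) were below 0. The list fell by camera on the slope (adjusted p = 8.45e-20; adjusted p = 0.286 with an estimated correlation). Within it, Laptm5 and C1qa, a complement C1q chain, had folds of -3.37 and -3.27 (-6.83 to -1.89), and Ctsd and Cd68, lysosomal proteins, -0.15 and -0.56 (-1.40 to 0.15 for Cd68, which includes 0). Inflammation and cytokine genes had medians of -0.75, -1.49, -2.52 and -2.00, with 12 of 12 measured members (27 listed) below 0 at 60 min (camera adjusted p = 2.76e-19, and 0.063 with an estimated correlation). Tlr2 and Il1a were lowest in that list, and Il1r1 and Nfkbia, an inhibitor of NF-kappa B, had folds of -0.50 (-2.55 to 0.89, which includes 0) and -1.47. All genes of the count table had at least 11 counts at 0 min, so members of either list gained only after HHT could not appear.

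Oligodendrocyte and myelin markers also fell, with medians of -0.61, -0.46, -0.97 and -1.36 and 19 of 21 members below 0 at 60 min (camera adjusted p = 1.40e-11; adjusted p = 0.063 with an estimated correlation). Cnp, a myelin enzyme, went from 9041 to 271 counts, a fold of -2.57 (-2.75 to -2.40), and Mog, a myelin surface protein, had a fold of -2.24. Bcas1, a protein of myelin-forming cells, had the opposite sign at 1.59 (1.48 to 1.71). Mbp, myelin basic protein, has no counts here, and its TPM was 6775 at 0 min and 22887 at 60 min. Astrocyte markers fell with medians of -0.37, -0.31, -0.52 and -0.59 and 20 of 22 members below 0 (camera adjusted p = 5.86e-04; adjusted p = 0.286 with an estimated correlation). Glul, glutamine synthetase, and Sox9, an astrocyte transcription factor, had folds of -1.63 and -1.70, while Ntsr2 had 0.87. Endothelial and mural markers had medians of 0.41, 0.86, 0.20 and 0.11 with no call (camera adjusted p = 0.713); Bsg was highest at 1.56 and Pecam1 lowest at -1.16. The medians at 60 min of the microglia, inflammation, oligodendrocyte, astrocyte and immediate early gene lists lay below all 10000 random lists, also when those were matched on CDS length. Adjusted over the list alone, 14 microglial, 11 inflammation, 13 oligodendrocyte, 1 astrocyte and 8 immediate early genes were lower on the TMM-scaled slope. In the same way 1 oligodendrocyte and 1 immediate early gene were higher. Adjusted over all genes tested, 0 members of these lists were called in either direction. The adjustment within a list takes no account of the 26 lists. Without the 0 min library the camera call ended for microglia (adjusted p = 0.273) and astrocytes (0.190).

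**Figure D4:**
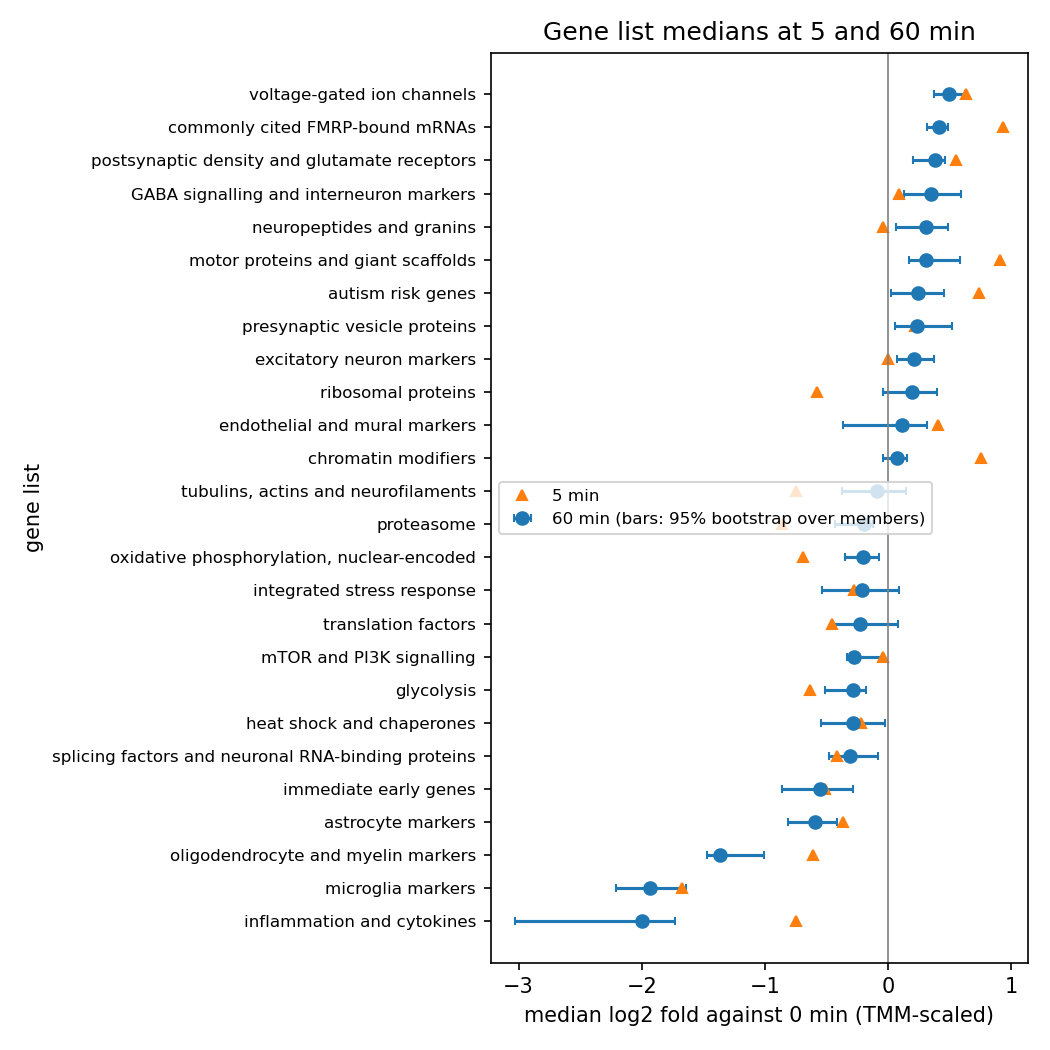
Median log2 fold against 0 min (horizontal axis, TMM-scaled) of 26 gene lists (vertical axis), 1 library per time. Circles are 60 min with 95% bootstrap intervals over members, which leave out differences between libraries, and triangles are 5 min; microglia and inflammation lists lie at -1.94 and -2.00 at 60 min and voltage-gated ion channels at 0.49.

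Several neuronal groups kept more footprints than the typical mRNA at 60 min. The list of commonly cited targets of FMRP, the RNA-binding protein lost in fragile X syndrome, had medians of 0.93, 1.23, 0.40 and 0.41, and 88 of its 108 members were above 0 at 60 min. Relative to other mRNAs it rose by camera on the slope (adjusted p = 0.0063; adjusted p = 0.828 with an estimated correlation), while scaled to mitochondrially encoded proteins 101 of the 108 members fell. Sptbn1, a spectrin beta chain, had 6048 counts at 0 min and 4179 at 60 min, a fold of 1.95 (1.90 to 2.01), and Macf1 had 1.54; Pde2a and Trrap had -1.09 and -0.62. Voltage-gated ion channels had medians of 0.63, 0.73, 0.48 and 0.49 with 37 of 45 above 0 (camera adjusted p = 0.0145; adjusted p = 0.594 with an estimated correlation), and Cacna2d2 and Kcnc1 were highest at 1.03 and 0.99. Postsynaptic density and glutamate receptor genes had medians of 0.55, 0.49, 0.35 and 0.38 with 42 of 52 above 0 (camera adjusted p = 0.0206; adjusted p = 0.594 with an estimated correlation). In that list the receptor subunit gene Grin2d had 1.78, and the scaffold gene Shank3 had 1.41 (1.24 to 1.58). Motor proteins and giant scaffolds had medians of 0.91, 1.51, 0.73 and 0.31 (camera adjusted p = 0.0198; adjusted p = 0.828 with an estimated correlation), from Sptbn1 at 1.95 to Myo6 at -0.89. GABA signalling and interneuron markers (medians 0.08, 0.14, 0.29 and 0.35) and neuropeptides and granins (-0.04, 0.07, 0.23 and 0.31) were also called higher, with camera adjusted p = 0.0125 and 0.0410 (adjusted p = 0.497 and 0.498 with an estimated correlation). Scaled to mitochondrially encoded proteins, 45 of 45 channel, 51 of 52 postsynaptic, 36 of 42 motor and scaffold, 18 of 20 GABA and 15 of 16 neuropeptide genes fell. Lhx6, an interneuron transcription factor, had 1.73, Penk, the enkephalin precursor, 1.33, and Gad2 -0.32. The FMRP-list members share 20 genes with the postsynaptic list, 17 with the motor and scaffold list and 9 with the channel list. The medians of these lists at 5 min went in large part with CDS length. Random lists matched on expression and CDS length had medians of 0.79 for the FMRP list and 0.43 for channels at 5 min. For the postsynaptic list and the motor and scaffold list they were 0.47 and 0.81. At 60 min they were, in the same order, 0.12, 0.044, 0.051 and 0.13. Without the 0 min library the FMRP and motor lists were called in the opposite direction, lower with time (adjusted p = 1.18e-06 and 2.39e-04), and the channel and postsynaptic lists lost their call with the opposite sign (adjusted p = 0.475 and 0.535), as the GABA list lost its call (0.0777). The neuropeptide call ended without the 5, 30 or 60 min library (0.0514, 0.106 and 0.150), and on minutes in place of log2 time those of the FMRP (0.415), motor (0.418), postsynaptic (0.270) and channel (0.265) lists, the first pair with the opposite sign. The motor call also ended once the length trend was removed (0.0882).

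Chromatin modifiers, a group named in the series' title along with splicing, had medians of 0.75, 1.11, 0.05 and 0.07 and no call (camera adjusted p = 0.681). That depended on the setting: the list was called lower on minutes in place of log2 time (adjusted p = 5.18e-05) and without the 0 min library (7.53e-12), and higher without the 60 min library (0.0477). Their median at 60 min lay at percentile 73.7 of random lists, and at percentile 39.1 of lists matched on CDS length. Tet3, Kmt2b, Kdm6b and Tet2 had folds of 1.18, 1.17, -0.96 and -1.14 at 60 min; Tet2 had 5 counts at that time, and its interval, -2.94 to 0.02, includes 0. Autism risk genes had medians of 0.74, 0.90, 0.37 and 0.24 with no call (camera adjusted p = 0.195), but the list was called lower without the 0 min library (0.0036) and higher without the 60 min library (0.0052). Splicing factors and neuronal RNA-binding proteins fell, with medians of -0.41, -0.41, -0.24 and -0.31 and 44 of 58 members below 0 (camera adjusted p = 0.0085; adjusted p = 0.594 with an estimated correlation). Srsf5 and Ptbp1, regulators of splicing, had folds of -1.98 and -1.69, while Cpeb2 and Rbfox2 had 0.84 and 0.62; Cpeb2 had the opposite sign on the TPM scale (-0.22). Without the 0 min library the splicing list had no call and the opposite sign (adjusted p = 0.340), and on minutes it had none (0.278).

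Immediate early genes, transcribed quickly after neuronal activity, fell, with medians of -0.51, -0.52, -0.53 and -0.55 and 25 of 34 members below 0 (camera adjusted p = 2.52e-04; adjusted p = 0.536 with an estimated correlation). Fos had a fold of -1.67 (-1.89 to -1.47) and Zfp36, which promotes mRNA decay, -2.20, while Jund had 1.57 and Arc, a synaptic plasticity gene, 0.92. Without the 0 min library the list had no call and the opposite sign (adjusted p = 0.584), and on minutes it had none (0.139). Heat shock and chaperone genes fell with a median of -0.29 at 60 min (camera adjusted p = 0.0446; adjusted p = 0.594 with an estimated correlation). In that list Bag3 had a fold of -2.31, and Hspa1a, with 35 counts at 0 min and 0 at 60 min, was at least 2.08-fold lower against a floor of 3 counts, while its counting interval ends at a log2 fold of -0.68. The list's median was -0.29 with Hspa1a at its bound, and its call ended without the 0 min (adjusted p = 0.900) or the 60 min library (0.0887), on minutes (0.212) and with the length trend removed (0.0551). Ribosomal proteins, of which 16 of 79 were measured, had medians of -0.58, -0.13, 0.32 and 0.20 and were called higher with time relative to other mRNAs (camera adjusted p = 0.0333; adjusted p = 0.816 with an estimated correlation), while 15 of the 16 fell when scaled to mitochondrially encoded proteins. The call ended without the 5, 30 or 60 min library (adjusted p = 0.122, 0.160 and 0.175). Rpl10a was highest at 1.38, and Rps3 lowest at -0.37 (-0.88 to 0.10, which includes 0).

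No call was made for the remaining lists on the slope as planned. Their medians at 60 min were -0.22 for translation factors, -0.21 for the integrated stress response, -0.20 for nuclear-encoded oxidative phosphorylation, -0.28 for glycolysis, -0.20 for the proteasome, -0.09 for tubulins, actins and neurofilaments (also with Tuba1c, at 0 counts at 60 min, set to its bound), -0.28 for mTOR and PI3K signalling, 0.24 for presynaptic vesicle proteins and 0.21 for excitatory neuron markers. Other settings did make calls. With the length trend removed, presynaptic and excitatory neuron genes were called higher (adjusted p = 0.0309 and 0.0309), and glycolysis, proteasome and mTOR genes lower (0.0230, 0.0284 and 0.0309). The proteasome list was called higher without the 0 min library (1.09e-05) but lower without the 5, 30 or 60 min library (0.0139, 0.0289 and 0.0032). Oxidative phosphorylation and tubulin genes were called higher without 0 min (4.08e-04 and 1.01e-04), glycolysis lower without 5 or 60 min (0.0365 and 0.0169) and with total count only (0.0439), and the integrated stress response lower without 60 min (0.0229). Eif5, an initiation factor, had a fold of -1.30, Aldoc, an aldolase, -1.23, and the neurofilament gene Nefh 1.19. Slc17a7, the vesicular glutamate transporter of excitatory neurons, had 0.83. Of the fixed genes, Fmr1 had a fold of -0.18 (-0.48 to 0.11), Camk2a 0.24, Eef2 0.56, Gfap -0.65 and Atf4 0.44.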

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

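The random lists matched on expression and CDS length were planned before the data were examined; the other tests and the screening limits in this part were chosen after the results were seen. Groups of 1 library allow no search for samples that stand apart from their group. What was searched was the TPM table for genes that the count table does not hold, with a TPM of at least 50 at 0 min and a gain at 60 min above the highest of the 6 mitochondrially encoded genes (5.13-fold; their lowest was 4.68-fold). Of 178 such genes, 10 passed. The screen used 60 min alone, and mitochondrial signal was taken as a yardstick without a test that it stayed constant. With a TPM limit of 20 there were 19 of 352, and with 100 there were 3 of 86, so the number depends on this limit.

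Kxd1, a gene of lysosome positioning, had the highest TPM of these genes, with 1943, 5916, 11243, 13516 and 13884 in time order, 7.15 times at 60 min. Gm26558 reached 15 times its 0 min TPM, Shisa5 7.21 times, Taf10 6.85 times, Nudt19 6.44 times, Pithd1 6.33 times, Igfbp6 6.24 times, Lrrc58 6.11 times, Scp2 5.58 times and Gm20431 5.23 times. At 5 min the TPM of Shisa5 (91 against 95), Taf10 (56 against 81) and Pithd1 (115 against 132) lay below that at 0 min, and that of Gm20431 was 119 against 91. TPM is a share of each library, and the count behind these values is not used here. The count table starts at a CDS of 603 nt, so genes outside it can be shorter. Where little of a CDS is left to count, few reads can give a high TPM. The CDS lengths of these genes were not checked, so their TPM is no measure of the number of footprints.

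Other orders of the 5 time labels were fitted for 100 orders, the real one included. For the TMM-scaled slope, 17 of the 100 orders gave at least as many genes as the real 1, with up to 447 in another order, so chance was not excluded for that count. In the order with 447 genes, the 10 and 5 min libraries took the earliest places and the 30, 60 and 0 min libraries the latest. This is the split of 5 and 10 min from the rest that the first principal component of log2 CPM shows. Such orders carry differences between the libraries, so this comparison cannot decide about chance, here or for lists. For lists called by camera, 40 of the 100 orders gave at least the real 14, with up to 20 in another order, and chance was not excluded either. For the slope scaled to mitochondrially encoded proteins, 1 of the 100 orders, the real one, gave 8859 genes; the highest other gave 8780. This decides nothing about chance, since the scaling moves all genes of a library by 1 factor and the median fold under it (-1.58, -1.86, -2.12 and -2.43) already follows the time order.

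The microglial list had a low share of footprints left at 60 min, as did the inflammation list. Short coding sequences alone are argued against, since the microglial median lay -1.87 log2 units from that of random lists matched on expression and CDS length. Immediate early genes, taken here as short-lived mRNAs, had a median 1.38 above the microglial one (bootstrap interval 0.88 to 1.79). Their own median at 60 min, -0.55, lay below all matched random lists, and mRNA levels were not measured in these libraries. The comparison therefore shows a deeper fall of the microglial list and leaves a general loss of short-lived mRNAs open. If more microglia in the 0 min slices were the only cause, the treated libraries would be level. With the length trend removed, 60 min against 5 min was -1.32 (-2.24 to -0.43) for inflammation genes, which is not level. For microglial markers it was -0.57 (-1.09 to 0.12). Each value compares single pools and its bootstrap runs over genes only, so a difference between the 5 and 60 min pools could give it too. More microglia in the 0 min slices therefore stays open for both lists. Differences between the other pools and a loss of these mRNAs in the slices were not tested.

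The mRNAs with a CDS of 8000 nt or more had no fewer footprints at 10 min than at 5 min. An error of a single mitochondrially encoded gene is argued against, because with each of 6 mitochondrially encoded genes as the scale the median ratio of 10 over 5 min stayed above 1, the lowest being 1.145 (bootstrap interval 1.12 to 1.15). An error that these 6 genes share stays open, since a factor off by 1.22 between the libraries would level these mRNAs and no other yardstick was measured. A difference between the slice pools at 5 and 10 min cannot be told apart from it: 111 of 123 such mRNAs were higher at 10 min, but each time has 1 pool. A slow entry of HHT into the slices, or slower elongation after 5 min, stays untested.

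The FMRP-listed mRNAs kept more footprints than the typical gene at 60 min. Long coding sequences alone are argued against, because the list's median lay 0.29 log2 units above that of random lists matched on expression and CDS length. Length was matched by quintile, so the longest mRNAs are matched only in part. The list, with a median CDS of 4767 nt, had a median deposited ratio of 0.243 at 60 min. Genes of 4000 nt to under 6000 nt had 0.197, and those of 8000 nt or more 0.240. Expression in neurons stays open, because the list lay only 0.17 (bootstrap interval -0.03 to 0.34) above 54 neuronal markers outside it, and the 2 cannot be told apart on this value. Length was not matched there. The markers came from excitatory, GABA and neuropeptide lists with median CDS of 1818, 1452 and 1345.5 nt. Over all genes the median log2 fold at 60 min was -0.03 in the shortest length quintile and 0.10 in the longest. The bootstrap runs over genes and leaves out differences between pools. Retention of ribosomes on these mRNAs remains an untested hypothesis in libraries of 1 genotype.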

How the results depend on the processing

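Alternatives with library factors from the deposited signal, the CDS length column, length-corrected camera and the trimmed end were chosen after seeing the data. No paired analysis was possible because each time point has 1 library. CDS length of the longest isoform in the reference annotation was not run, since the annotation table used here gives no CDS lengths. Against 0 genes higher and 1 lower on the slope, the counts lower were 3 with DESeq2's size factors, 3 for 0 min against all treated libraries, 4 on the rank of time and 0 by limma on log2(TPM + 1) and on log2(TPM + 0.1). They were 36 higher and 37 lower by the DESeq2 Wald test, 22 and 57 with total count only, and 5 and 19 with the upper quartile. Lower calls numbered 8859 when scaled to mitochondrially encoded proteins and 8900 with the deposited library factors, both because a common factor per library then enters. With each library left out in turn, higher calls ranged from 0 to 364 and lower calls from 0 to 854, the most without 0 min. For the other moves the cause was not tested.

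Genes at least 2-fold higher and lower, in time order, were 0 and 5939, 1 and 6333, 0 and 7278, and 0 and 7311 scaled to mitochondrially encoded proteins. With the deposited factors they were 0 and 5820, 1 and 6345, 0 and 7280, and 0 and 7312. With at least 500 counts they were 290 and 144, 589 and 104, 94 and 86, and 90 and 91, since fewer genes are counted. With at least 20 counts they were 526 and 514 at 30 min and 585 and 569 at 60 min. Total count only gave 87 and 1080 at 5 min and 480 and 1194 at 10 min, and the upper quartile 218 and 681 at 5 min. On log2(TPM + 1) there were 884 higher at 5 min, 646 lower at 10 min and 620 lower at 60 min, and on log2(TPM + 0.1) 890, 651 and 624. On those 2 scales the fold at 60 min changed sign for Cpeb2 (-0.22 and -0.22), Doc2a (0.061 and 0.061) and Enpp2 (-0.031 and -0.031); the cause was not tested.

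Of the 7 lists called higher and 7 called lower by camera, 0 and 0 remained called with an estimated correlation; fry called 1 and 3, camera with the length trend removed 8 and 9, and minutes in place of log2 time gave 3 higher and 5 lower, with chromatin modifiers among the latter (adjusted p = 5.18e-05) and the calls of the immediate early (0.139), splicing (0.278), heat shock (0.212), postsynaptic (0.270) and channel (0.265) lists ended. The slope of the FMRP list and of motor proteins turned negative on minutes (adjusted p = 0.415 and 0.418). Without 0 min the slope changed sign for 14 of 26 lists, for 10 of them with a call before or after, and without 5, 30 or 60 min for chromatin modifiers (0.931, 0.511 and 0.0477), which without 0 min were called lower (7.53e-12). With each library left out in turn, the adjusted p of these 10 and of chromatin modifiers ranged from 9.82e-08 to 0.0018 for the FMRP list (1.18e-06 without 0 min), 0.0036 (lower, without 0 min) to 0.147 for autism genes (0.0052 and higher without 60 min), 0.0022 to 0.340 for splicing factors, 0.0079 to 0.535 for postsynaptic genes, 0.0033 to 0.475 for channels, 5.84e-06 to 0.584 for immediate early genes, 4.08e-04 to 0.782 for oxidative phosphorylation, 1.09e-05 (higher, without 0 min) to 0.090 for the proteasome (lower in the other 4, with calls in 3), 1.01e-04 to 0.935 for tubulins, 5.86e-07 to 0.0128 for motor proteins (2.39e-04 without 0 min) and 7.53e-12 to 0.931 for chromatin modifiers. The percentile of chromatin modifiers passed from 73.7 to 39.1 with matching on CDS length. The inflammation and oligodendrocyte lists kept their call with each library left out, on minutes and with fry.

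The rank correlation with length at 5, 10, 30 and 60 min was 0.785, 0.579, 0.151 and 0.097 with a mean of at least 50 counts, 0.659, 0.429, 0.093 and 0.044 on log2(TPM + 1), and 0.671, 0.427, 0.086 and 0.034 given mean expression; with the CDS length column it was 0.728 and 0.499 at 5 and 10 min. The rank correlation between libraries at 0 and 60, 5 and 10, and 30 and 60 min was 0.928, 0.953 and 0.963 on log2(TPM + 1), and 0.900, 0.960 and 0.975 with at least 50 counts. Depth limits the 60 min values most, with a median of 38 counts per gene.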

Other observations

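The first principal component of log2 CPM did not follow time. It holds 42.3% of the variance and sets 5 min (33.0) and 10 min (30.6) against 0 min (-19.6), 30 min (-17.9) and 60 min (-26.0). The second holds 36.0%, runs in time order and sets 0 min (41.6) and 5 min (12.8) against 10, 30 and 60 min (-15.5, -18.1 and -20.7).

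Among aldolases, Aldoa had a log2 fold of 0.04 (-0.01 to 0.09) at 60 min and Aldoc -1.23. Kl, the klotho gene of choroid plexus, had 88 counts at 0 min and 62 at 60 min (1.92), and Foxj1, a regulator of cilia, had 0.76 (-0.19 to 1.76, which includes 0); their list had 3 measured members and was not tested. Hist1h1d and Hist1h1e, linker histones, had 5 and 3 counts at 60 min and folds of -0.73 (-2.52 to 0.48) and -1.10 (-3.65 to 0.33), whose intervals include 0.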
